A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

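The series holds 8 two-colour arrays of 4 RNA samples of a Halobacterium salinarum NRC-1 ura3 and kinA2 deletion strain, each hybridised against the same reference RNA and repeated with the dyes exchanged. The deposited scanner tables give the intensity of each spot and of its local background, in Alexa 532 and Alexa 647, as neither background-subtracted nor normalized values, per the file headers. Each dye has columns ending in H and in L, and the H columns, which are brighter, were used. That H and L stand for high and low gain of the scanner is inferred from the values. A spot confidence score from 0 to 100 is given in the deposited tables, and how it was computed is not given in the sources used here. The authors also deposited a value table in log10 ratios. Comparison with the spot values showed that its numbers are the log10 of Alexa 532 over Alexa 647 and that its entries follow the raster order of the spots. In this order its values correlated with the recomputed ratios at an r of 0.957 to 0.987 on 7 arrays. On low oxygen, light replicate 2 the r was 0.295, and 0.886 without 3515 entries of exactly 0. The medians of its columns were 0.148 and 0.122 for high oxygen, light replicates 1 and 2, 0.152 and 0.106 for high oxygen, dark, 0.177 and 0 for low oxygen, light, and 0.126 and 0.0949 for low oxygen, dark, so the columns are not centred. The table leaves 645 spots empty on each replicate 1 array and 594 on each replicate 2 array. The software of the scanner and the way the authors made these values are not given in the sources used here.

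Spot means of the H columns were background-corrected with normexp (offset 50) and normalized within arrays by global loess, in R 4.3.3 with limma 3.58.1. Each array has 10752 spots, read as 2688 features of 4 spots, which were averaged. Ratios were turned to sample over reference by the dye labels, and the 2 arrays of a sample were averaged, since they are technical repeats. limma was fitted to the 4 sample means with an intercept, oxygen and light, which leaves 1 residual degree of freedom, followed by empirical Bayes moderation. Benjamini-Hochberg adjustment ran over all 2688 features, and features under 5% FDR are called. The p-values and SE measure only what oxygen and light leave unexplained between these 4 samples, moderated across features. This includes any light by oxygen term. Differences between oxygen levels, between light and dark and between the 2 arrays of a sample do not enter this spread. A light by oxygen term could not be tested with 1 sample per condition. A feature counts as well above background in a channel when at least 2 of its 4 spots exceed the local background median by more than 2 background SD. A gene has a measured level when it met this on at least 1 array on each side of a comparison, so its other arrays may be near background. Where it met this on 1 side only, the fold is given as a bound, and where it met it on neither side no fold is given. Spot medians over background medians ranged from 1.67 to 2.74 in Alexa 647 and from 0.895 to 1.36 in Alexa 532 across arrays.

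Gene symbols came from the probe table, which names 133 features, and the other features were tested without a name. All 133 symbols were found in the reference table, which belongs to another strain, and 0 of its identifiers matched, so no position is given. In each comparison the named genes are the called genes with 1 direction in all samples and both dye orientations, up to 10 in each direction with the largest values, filled up with the largest values that meet the sign conditions. To these come the 2 members with the largest values in each list with at least 3 measured members, and kinA2, pyrF, bop, bat, arcA, arcB, arcC, dmsA, gvpA, phr1 and phr2 where measured. For the light by oxygen difference they are the 5 largest values in each direction among those with 1 sign in both dye orientations. The text gives those with a measured level first. Sets of genes were tested with camera, with a correlation preset to 0.01 and, beside it, estimated. The estimated version rests on 1 residual degree of freedom, so a list that fails it is not shown to be unchanged. Of 23 lists fixed by symbol, 15 had a member and 8 had at least 3, which were tested. Another 5 lists were formed after the symbols and values were seen. The comparisons, tests, lists, rule for named genes and most alternatives were chosen before the data were examined.

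The alternatives were no background correction or subtraction, median or print-tip loess normalization, Aquantile or scale normalization between arrays, the authors' value table, leaving out the dimmest 25% of features or spots with a confidence below 100, the median of spots, eBayes with trend and robust, all 8 arrays with the sample as random block or with a dye term, which is also the replicate block since dye orientation, replicate number and array series coincide, single factors, and leaving out each array and each sample. Chosen after seeing the data were the L columns, the brightest 50% of features, leaving out a slide corner of 48 features, features above background in some channel, leaving out 319 features with an empty cell in the authors' value table with or without weight 0 in the loess curve, and each dye orientation alone. The fit was tested on simulated data with 20 draws per setting, in which 200 of the 2688 features were changed unless stated otherwise. At a log2 size of 1, 8.63% of the calls for light, 8.51% of those for oxygen and 8.24% of those against the reference were false on average, and at a size of 0.5 these shares were 11.9%, 9.81% and 8.51%, all above the nominal 5%. With no change at all, 50% of the draws for light, 55% of those for oxygen and 65% of those against the reference still held a call, with at most 13, 13 and 14 calls. These figures and the recovery rates come from simulations with a dye bias equal in both orientations. Simulated dye bias that differed between orientations, with no strain effect, gave a median of 250.5 calls against the reference. Correlations across features carry bootstrap intervals from 2000 draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.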

Results

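RNA from a Halobacterium salinarum NRC-1 strain that lacks the genes ura3 and kinA2 was compared on spotted two-colour arrays with RNA from a common mid-log reference culture of NRC-1. The strain was grown in rich medium to mid-log phase under 4 conditions that cross oxygen with light, with 1 sample per condition. High oxygen was set by shaking at 210 rpm, and low oxygen by shaking at 100 rpm in a stoppered flask. Dark cultures were kept in painted flasks. Each of the 4 samples was measured on 2 arrays with the dyes exchanged, which makes 8 arrays. The 2 arrays of a sample are technical repeats of the same RNA, so each condition has no biological replicate. Replicate 1 carries the sample in Alexa 532 and replicate 2 carries it in Alexa 647. The number of arrays limits the precision of every value. In the sample channel, between 412 and 1114 of 2688 probe features per array lay well above background. A gene symbol was given for 133 features, and between 39 and 83 of these lay above background in the sample channel of an array. The deleted kinA2 and the genes bop, gvpA, dmsA, arcB, phr1 and phr2 were not among the named features and are not analysed here.

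The mean of the deletion strain over all 4 samples was set against the reference RNA, a comparison in which strain, culture and growth conditions differ together. The 2 ribosomal protein genes with a name were both lower in the deletion strain, which held in each of the 7 other scalings tried. The gene rpl12p, for a protein of the large ribosomal subunit, was 1.34-fold lower (log2 difference -0.42 ± 0.07 SE, n = 4 samples, adjusted p = 0.0208, lower on 8 of 8 arrays). The gene rpmC, for another large subunit protein, was 1.33-fold lower (log2 difference -0.41 ± 0.10 SE, adjusted p = 0.0494, lower on 7 of 8 arrays). The chaperone gene dnaK was 1.27-fold lower (log2 difference -0.34 ± 0.06 SE, adjusted p = 0.0259, lower on 8 of 8 arrays). The gene arcC, for the carbamate kinase of arginine fermentation, was 1.31-fold higher (log2 difference 0.39 ± 0.06 SE, adjusted p = 0.0217, higher on 8 of 8 arrays). The other named gene of this pathway, arcA, was not called, at 0.05 ± 0.08 SE (limma adjusted p = 0.713). Its value was -0.09 with the sample in Alexa 532 and 0.19 with it in Alexa 647.

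Another 2 named genes with a measured level on both sides were lower in the deletion strain. The gene panB was 1.26-fold lower (log2 difference -0.33 ± 0.06 SE, adjusted p = 0.0267, lower on 7 of 8 arrays). The gene hemA, for the first enzyme of tetrapyrrole synthesis from glutamyl-tRNA, was 1.22-fold lower (log2 difference -0.28 ± 0.06 SE, adjusted p = 0.0405, lower on 8 of 8 arrays). The values of rpl12p were -0.40 with the sample in Alexa 532 and -0.45 with it in Alexa 647. Those of dnaK were -0.31 and -0.38, and those of hemA were -0.25 and -0.32. The orientations lay further apart for rpmC at -0.20 and -0.62, for panB at -0.05 and -0.62, and for arcC at 0.61 and 0.16. With features that have an empty cell in the authors' value table left out, an alternative chosen after seeing the data, rpl12p and arcC passed at an adjusted p of 0.0479. Under the same alternative, dnaK and panB had an adjusted p of 0.0531, hemA 0.0649 and rpmC 0.0759. With these features also given weight 0 in the loess curve, chosen after seeing the data too, all 6 passed (adjusted p from 0.0162 to 0.0355). Over the 31 alternatives run for single genes, some of them chosen after seeing the data, the 6 genes kept their sign, with rpl12p between -0.52 and -0.17, dnaK between -0.45 and -0.11, hemA between -0.37 and -0.17 and arcC between 0.12 and 0.46, and their adjusted p ranged from 0.000632 to 0.494. All 6 fell short of the threshold under print-tip loess (adjusted p from 0.0638 to 0.0851), under background subtraction (0.494) and in the L columns of the scan (0.228 to 0.388). With 1 of the 8 arrays left out rpmC passed in 2 fits, rpl12p, dnaK and arcC in 1 and panB and hemA in 0. These fits keep 1 sample in a single dye orientation, where a bias of dye or array series is not cancelled. They therefore do not show whether a call rests on 1 array. With 1 sample left out and the intercept alone none of the 6 passed.

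**Figure D1:**
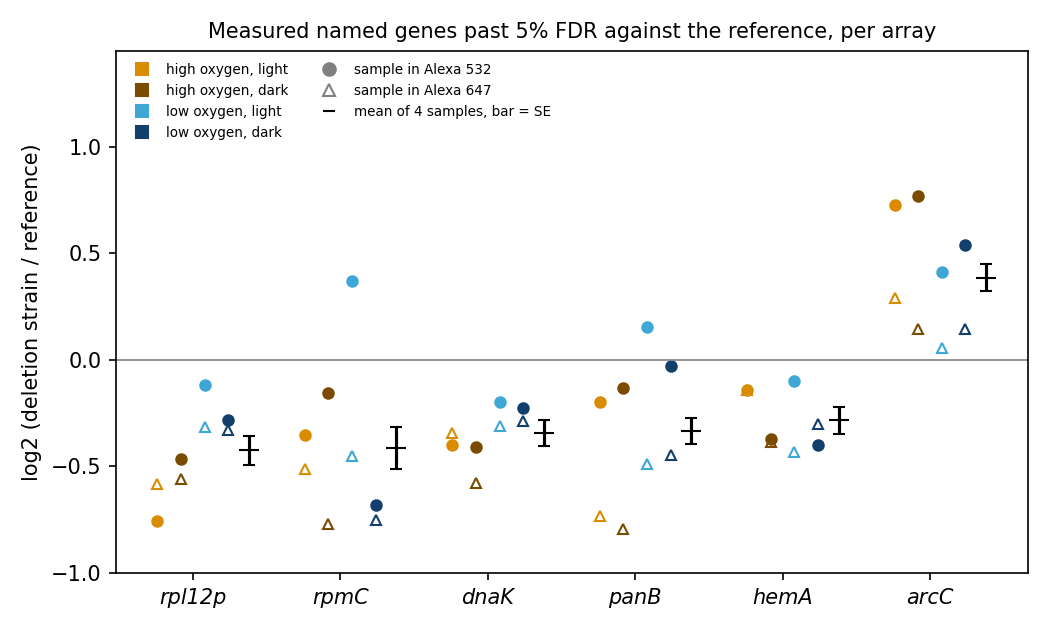
Log2 ratio of deletion strain to reference on each of the 8 arrays for the 6 named genes that were measured in both RNAs, passed 5% FDR and kept 1 direction in all 4 samples and both dye orientations. Points are arrays, coloured by condition and shaped by the dye of the sample, and black bars are the mean of 4 samples ± SE. All 8 values of rpl12p, dnaK and hemA lie below 0 and all 8 of arcC lie above 0.

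The product of pyrF is the orotidine phosphate decarboxylase of pyrimidine synthesis, and pyrF is the archaeal name of the deleted ura3. Its signal was not well above background in any channel of any array, so no fold is given. Its log2 difference was -0.89 ± 0.07 SE (adjusted p = 0.0154), lower on 8 of 8 arrays, but 0.23 when computed from the authors' value table. The purine synthesis gene purF was at least 1.04-fold lower, because its sample signal was near background. The phenylalanyl-tRNA synthetase gene pheS and the glycyl-tRNA synthetase gene glyS were called lower at log2 differences of -0.30 and -0.26, with a sample signal too dim for a fold. The direction of glyS turned under background subtraction, at 0.56, and in the authors' value table, at 0.01. Further called genes were purB, folP, gyrB and phoU, all 4 higher and in the same slide corner, and each has an empty cell in the authors' value table. Features with such a cell sit at fixed print positions and may be blank or control spots, which the sources used here do not settle, so these values may not be those of the named genes. Their log2 differences were 1.14, 1.04, 0.84 and 0.50, where purB and gyrB were above background in no channel and folP, with a reference signal near background, was at least 1.29-fold higher, and that of phoU was 1.61 in one dye orientation and -0.60 in the other, and turned to -0.21 under print-tip loess and -0.64 under background subtraction. In the L columns phoU, gyrB and folP turned to -0.31, -0.09 and -0.05. The value of purB turned to -0.63 under background subtraction and to -0.48 in the authors' value table.

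All 6 genes of the chaperone and proteasome list were lower than in the reference, with a median log2 difference of -0.24 (-0.19 with the sample in Alexa 532 and -0.27 in Alexa 647). Of these, dnaK and panB, 2 of the 6, passed the test over all features and 3 when adjusted over the list alone. The gene panB entered the list by the start of its symbol, and whether it belongs there was not settled. As a set they did not pass (limma camera p = 0.0105, adjusted p = 0.0837 over 8 lists, adjusted p = 0.98 with an estimated correlation). The direction held for 5 of the 6 in the authors' value table and in the L columns of the scan. All 4 named chemotaxis genes had positive values with a median of 0.14, among them cheB at 0.16 and cheA at 0.14, and none passed the test (camera adjusted p = 0.639). All 4 had negative values in the authors' value table. All 5 named genes of the citrate cycle had negative values with a median of -0.04, led by the malate dehydrogenase gene mdh at -0.11, but 1 of 5 kept 1 sign in both dye orientations, whose medians were -0.20 with the sample in Alexa 532 and 0.01 in Alexa 647, and none passed (camera adjusted p = 0.924). Of the 7 named Htr transducer genes, which encode sensors of phototaxis and chemotaxis, 4 had positive and 3 negative values, with htr7 at -0.23 and htr2 at -0.17 (camera adjusted p = 0.943). Of the 8 purine and pyrimidine genes 4 had positive and 4 negative values, of which purB was called higher and purF lower (camera adjusted p = 0.976). The lists for rhodopsin and carotenoid genes, for DNA repair and for cobalamin synthesis had no member past the threshold, and each had a camera adjusted p of 0.976. Within them, hop, the halorhodopsin gene, had a value of 0.17, uvrA -0.12, and cobN 0.13.

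Across all 2688 features, limma called 677 at 5% FDR, 435 higher and 242 lower in the deletion strain, and 20 of them were named. The test had 1 residual degree of freedom, moderated by 3.24 prior ones. Of the 435 higher calls, 304 lie in the 319 features that have an empty cell in the authors' value table. Of those 319 features, 17 were above background in the sample channel of any array and 10 in the reference channel. With these features left out, 161 of the remaining 2369 passed, 54 higher and 107 lower, and with them also given weight 0 in the loess curve 412 passed, 222 higher and 190 lower. Both alternatives were chosen after seeing the data. Of the 677 calls, 304 had 1 direction in both dye orientations, and outside the features with an empty cell this held for 268 of 373. Across features, the log2 ratios of the orientations had a Pearson r of -0.521, and of -0.237 over the features with no empty cell. Features are not independent replicates. The count was 0 with background subtraction, at which 210 of 2139 features had an unadjusted p under 0.05, and 13 with print-tip loess. Under print-tip loess 640 of the 677 called features kept their sign, 462 of them had an unadjusted p under 0.05, and 408 features passed limma at 10% FDR, against 898 at 10% FDR with global loess. Leaving out 1 array, which keeps its sample in a single dye orientation, gave between 0 and 736 calls.

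**Figure D2:**
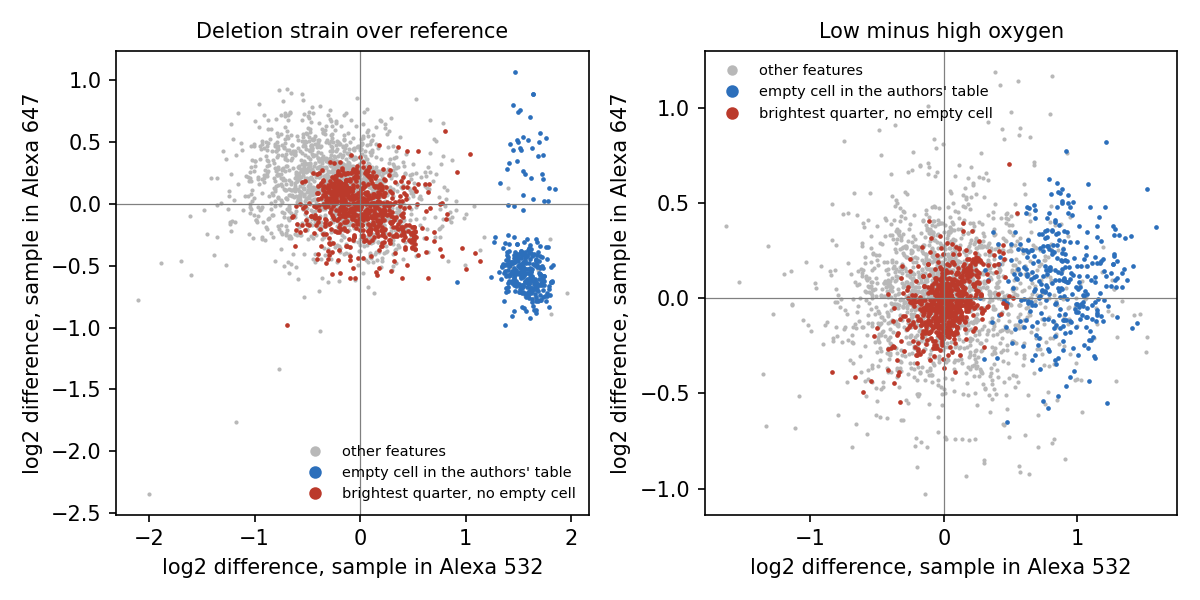
Log2 differences of 2688 features from the arrays with the sample in Alexa 532 (x axis) against those with the sample in Alexa 647 (y axis), for the deletion strain over the reference (left) and for low minus high oxygen (right). Each point is a feature. Blue marks the 319 features with an empty cell in the authors' value table, which lie apart on the left panel, red marks the others among the brightest 25% of features, and grey the rest.

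Low and high oxygen were compared over light and dark, which asks which transcripts of this strain depend on the aeration of the culture. Positive values are higher at low oxygen. Among named genes with a measured level, no empty cell in the authors' value table and 1 sign in light, in dark and in both dye orientations, the largest positive value was that of rpl12p, at 0.33 ± 0.13 SE (n = 4 samples, positive in 4 of 4 comparisons of single arrays). The gene panB followed at 0.26 ± 0.12, and thiC, of thiamine synthesis, at 0.26 ± 0.15. The value of thiC was 0.52 with the sample in Alexa 532 but 0.0019 in Alexa 647, and it was near 0 in the authors' value table. The largest negative values under the same conditions were those of the transducer gene htr8 at -0.30 ± 0.14, of pheA, of phenylalanine synthesis, at -0.28 ± 0.12, and of glmS, of glucosamine phosphate synthesis, at -0.21 ± 0.13. Of the 4 low and 4 high oxygen arrays, htr8 and glmS were well above background on 1 and 3 and pheA on 2 and 2. The gene panB was so on 3 and 3, and rpl12p and thiC on 4 and 4. None of these passed the test (adjusted p from 0.354 to 0.522).

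Of the 7 named Htr transducer genes, 6 had lower values at low oxygen, with a median of -0.20, among them htr8, htr7 at -0.25 and htr6 at -0.20. Only 2 of the 7 kept 1 sign in both dye orientations, whose medians were -0.26 with the sample in Alexa 532 and 0.04 in Alexa 647, and htr7 had values of -0.65 and 0.14. As a set they did not pass (limma camera adjusted p = 0.236). Both ribosomal protein genes had positive values with a median of 0.20, though 1 of them turned negative in the L columns. In arginine fermentation, arcA, the arginine deiminase gene, had a value of 0.07 ± 0.16 and arcC of -0.19 ± 0.13. Of the rhodopsin and carotenoid genes, hop had a value of -0.18 ± 0.14, and bat, a regulator gene, was not above background (camera adjusted p = 0.941). Citrate cycle genes had positive values in 4 of 5 cases, led by sucC at 0.08 and citZ at 0.07, but 1 of 5 kept 1 sign in both dye orientations, and negative values in 5 of 5 in the authors' value table (camera adjusted p = 0.941). The other lists did not pass either. The camera adjusted p was 0.702 for chemotaxis genes, with cheR at -0.06, and 0.702 for chaperone and proteasome genes. It was 0.575 for DNA repair genes, 0.598 for cobalamin genes, with cobN at -0.14, and 0.702 for purine and pyrimidine genes.

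limma called 0 of 2688 features for oxygen at 5% FDR, with 412 at an unadjusted p under 0.05 where 134.4 would be expected by chance, and a smallest adjusted p of 0.263. With the features that have an empty cell left out, 200 of 2369 had an unadjusted p under 0.05 and 0 passed. The only count above 0 came from the 8 arrays with the sample as a random block, at 15 calls. Of the 4 genes of the slide corner, phoU had a value of 0.68 ± 0.12 (adjusted p = 0.263), where all 48 features of that corner had an oxygen median of 0.51, which was -0.06 with print-tip loess. The oxygen differences of the dye orientations correlated across features with an r of 0.109, and of 0.455 in the brightest 25%. Over the 133 named features r was -0.0745 (bootstrap interval -0.284 to 0.137), and 51 of them kept 1 sign in both orientations. The named genes given above with the largest oxygen values were chosen for 1 sign in both. The oxygen difference in light correlated with that in dark at an r of 0.310 over all features and of 0.144 over those with no empty cell. With the sample in Alexa 532 alone r was 0.354, and with it in Alexa 647 alone it was -0.020.

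Light and dark were compared over the oxygen levels, which asks which transcripts depend on light. Positive values are higher in light. Among measured named genes, the transducer gene htr7 had the largest positive value, 0.51 ± 0.17 SE (n = 4 samples, 1.42-fold, positive in 4 of 4 comparisons of single arrays, 0.51 in each dye orientation). The ribosomal gene rpmC followed at 0.35 ± 0.20, surE at 0.26 ± 0.13 and msrA, for a methionine sulfoxide reductase, at 0.23 ± 0.15. The largest negative values were those of the aspartyl-tRNA synthetase gene aspS at -0.34 ± 0.16, the arginine synthesis gene argH at -0.29 ± 0.13, and asd at -0.26 ± 0.12. Of the 4 light and 4 dark arrays, htr7, surE and asd were well above background on 1 and 2, and msrA on 1 and 1. The gene rpmC was so on 2 and 2, aspS on 3 and 3 and argH on 4 and 4. In the authors' value table htr7 turned to -0.06, surE to -0.14 and msrA to -0.26, and in the L columns rpmC turned to -0.04 and argH to 0.37. None of these passed the test (adjusted p from 0.808 to 0.851).

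Of the rhodopsin genes, hop had a light-dependent value of 0.11 ± 0.14, which over the alternatives ranged from -0.22 to 1.31, and the sensory rhodopsin gene sop1 one of -0.10 ± 0.15, which ranged from -0.36 to 0.14 (camera adjusted p = 0.827). All 4 chemotaxis genes had negative values with a median of -0.07, but 2 of 4 kept 1 sign in both dye orientations and all 4 had positive values in the L columns (camera adjusted p = 0.791). Of the Htr transducer genes 6 of 7 had positive values with a median of 0.06, but 4 of 7 kept 1 sign in both dye orientations and 3 of 7 were positive in the authors' value table and under background subtraction (camera adjusted p = 0.791). Citrate cycle genes had negative values in 4 of 5 cases, led by citZ at -0.17 and icd at -0.13, and in 2 of 5 in the L columns (camera adjusted p = 0.791). The camera adjusted p was 0.827 for chaperone and proteasome genes, with dnaJ at -0.16, and 0.827 for cobalamin genes, with cobN at 0.16. It was 0.791 for DNA repair genes and 0.791 for purine and pyrimidine genes. The value of arcA was -0.20 ± 0.16 and that of arcC -0.03 ± 0.13.

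limma called 0 of 2688 features for light at 5% FDR, with 159 at an unadjusted p under 0.05 where 134.4 would be expected by chance, and a smallest adjusted p of 0.808. None of the 33 alternatives, counted without Aquantile normalization, gave a call, with between 31 and 392 features at an unadjusted p under 0.05. Recovery was tested on simulated log ratios of this design with a dye bias equal in both orientations, where 200 of 2688 features were changed. Smaller numbers of changed features were not simulated, so the rates do not show that a few such changes would be called. A change of 1 on the log2 scale was recovered in 99.5% of changed features for light and 99.7% for oxygen. For a change of 0.5 the shares were 54.3% and 45.1%, with no recovery in 2 and 4 of 20 draws. The change was added after normalization, so these rates do not show what would be seen in features near background. The light differences of the dye orientations correlated across features with an r of 0.026, and of 0.338 in the brightest 25%. Over the 133 named features r was 0.122 (bootstrap interval -0.0607 to 0.287), and 76 of them kept 1 sign in both orientations. The light difference at high oxygen correlated with that at low oxygen at an r of 0.041.

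The light effect at low oxygen minus that at high oxygen asks whether the factors act together. With 1 sample per condition it has no test, and only values are given. The values given are of named genes with a measured level in all 4 samples and 1 sign of the difference in both dye orientations. The gene gdhA1, for a glutamate dehydrogenase, had a difference of 0.90, from a light effect of 0.26 at low oxygen and -0.65 at high oxygen. The gene speB had a difference of 0.63, from 0.35 and -0.28. The chaperone gene dnaJ had a difference of -0.51, from -0.41 and 0.10. Over all features the SD of this difference was 0.388 on the log2 scale, and the differences of the dye orientations correlated with an r of -0.0668, and of 0.151 in the brightest 25%.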

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

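All tests of explanations here were chosen only after the result they measure was seen, except that of the position at the slide edge.

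In 3 named genes with a measured level in all 4 samples the light effect went opposite ways at the 2 oxygen levels in both dye orientations. The light effect at low oxygen minus that at high oxygen was 0.90 for gdhA1, 0.63 for speB and -0.51 for dnaJ on the log2 scale. The difference was not tested, because each condition has 1 sample. The pairs of arrays behind each value are technical repeats. The 3 genes were picked from the largest values with 1 sign of the difference in both dye orientations, and among these for opposite light effects in both. Their agreement across arrays was therefore a condition of the choice. For dnaJ the light effect at high oxygen was 0.013 with the sample in Alexa 532 and 0.18 in Alexa 647. Between dye orientations the difference correlated at an r of -0.0668 (95% bootstrap interval -0.112 to -0.0210) over all features. Over named features r was -0.106 (-0.260 to 0.0838).

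Ratios of the deletion strain to the reference went opposite ways between dye orientations for most features, with an r of -0.521 over all 2688. Arrays whose dyes had not been exchanged would turn the oxygen effect too, but in the brightest 25% of features that effect correlated at 0.455 between orientations. A difference between strain and reference RNA would give a positive r, and the r of -0.521 (95% bootstrap interval -0.569 to -0.466) is negative. That is the pattern itself, so it is no separate test of this explanation. With print-tip loess r was -0.529 over all features, -0.173 (-0.253 to -0.0874) with no empty-cell features and 0.0452 (-0.0616 to 0.152) in the brightest 25%. Such a difference may be present beside the cause of the opposite ratios. The 319 features with an empty cell in the authors' value table may account for part of the pattern, since r was -0.237 (95% bootstrap interval -0.299 to -0.168) without them, an interval that spans the bound set for this explanation and leaves its share open. Dye orientation coincides with the array series, so a bias of the dyes and one of the array series cannot be told apart.

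The 677 calls against the reference may have several sources. Of the features called higher, 69.9% (exact 95% interval 65.3 to 74.2) have an empty cell in the authors' value table, where their share of all features is 11.9%, and nearly all of these are at background level, so these calls give no reason to infer expressed genes. A bias of dye or array series that the exchange of dyes did not cancel stays open for the other calls: among features with no empty cell and an unadjusted p under 0.05 in one orientation at most 32.6% kept their sign in the other (37.6% with print-tip loess), but 268 of the 373 calls among them had 1 sign in both, a share that selection on the mean of both orientations raises. Print-tip loess shrank the called values to a median ratio of 0.735 (0.693 to 0.763), an interval that leaves open how much belongs to print blocks. Differences between strains stay open for rpl12p, dnaK, hemA and other genes with 1 direction in both orientations, and were not tested apart from culture and reference.

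The high values of purB, folP, gyrB and phoU may be a property of their print block, of the slide edge, or of spots with an empty cell in the authors' value table, which all 4 have. These genes share a slide corner of 48 features, whose median was 0.95 against the reference. The corner is a part of the print block, and the rest of the block was not examined. The position at the slide edge would raise the first printed copies over the second, which lie nearer the slide centre. The first lay 0.0909 above the second on the log2 scale (interval 0.0557 to 0.151), with corner medians of 1.01 and 0.867. The difference has the predicted direction but is small beside the corner median of 0.95. An edge effect that reaches both copies alike would not show in it, so the slide edge stays open. The 4 genes had a median of 0.936, against 0.948 for the other corner features, and 41 of the 48 features were called. From the median of the others, purB lay 0.473, folP 0.22, gyrB -0.28 and phoU -1.11 SD, so none stood above it by more than 0.473 SD. Whether the 4 genes changed themselves stays open, since purB and gyrB were not above background. With a curve per print block, the corner median was 0.15. Such a curve lowers an offset shared within a block whatever its cause, so it cannot tell a block effect from blank or control spots.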

How the results depend on the processing

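The L columns, the brightest 50%, the features above background, the slide corner, the features with an empty cell in the authors' value table and the single dye orientations for the counts, and for single genes the intercept alone with or without a sample left out, were alternatives chosen only after the data were seen. Aquantile normalization leaves log ratios as they are and is not counted below. Counts of 0 held for light in 33 of 33 alternatives and for oxygen in 32 of 33, with a limma count of 15 for oxygen with the sample as a random block, where the correlation between the 2 arrays of a sample was -0.78. Against the reference the count of 677 became 1161 with that block, 446 with scale normalization, 443 with the intercept alone, 433 without the dimmest 25% of features, 13 with print-tip loess and 0 with background subtraction (210 of 2139 at an unadjusted p under 0.05). It was 0 in the L columns (570 at an unadjusted p under 0.05), 269 in the brightest 50%, 202 in features above background, 161 without features with an empty cell and 412 with these also at weight 0 in loess. Fewer features tested explain part of the drop where features were left out, and for the other settings the cause was not tested. Without one array the count ranged from 0 to 736, at 736 without high oxygen, light replicate 2, at 96 without high oxygen, dark replicate 1, and at 0 or 1 for the other arrays. In these fits 1 sample is left in a single dye orientation, where a bias of dye or array series is not cancelled. Without one sample, which also needs the intercept alone, it ranged from 11 to 222 against the 443 of the intercept alone with all samples, where the rest are assumed to vary alike. The chaperone and proteasome list passed, as 1 list of 8, under subtraction, scale, the authors' value table, the random block, the replicate block and on leaving out any replicate 1 array (range 0 to 1). With an estimated correlation it had a camera adjusted p of 0.98, which rests on 1 residual degree of freedom and cannot decide on the set.

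Of the 20 named genes called against the reference, values that reversed were purB at -0.63, phoU at -0.64, glyS at 0.56, nadA at 0.73 and dcd at 0.14 under subtraction, nadA at 0.025 with no background correction, phoU at -0.21 with print-tip loess, folP at -0.051, gyrB at -0.088 and phoU at -0.31 in the L columns, and purB at -0.48, pyrF at 0.23, glyS at 0.010, mch at 0.012, dcd at 0.14 and nadA at 0.12 in the authors' value table. The cause was not tested. Their other values kept their direction, of which 222 stayed past the threshold and 100 did not. On leaving out 1 array 21 stayed past it and 139 did not, and on leaving out 1 sample 7 did and 73 did not. The oxygen effect in light and in dark correlated at 0.208 under median normalization, 0.354 with the sample in Alexa 532 alone, -0.020 in Alexa 647 alone and 0.144 without features with an empty cell. For the light effect r was -0.00418 under median normalization and -0.054 in Alexa 532 alone. The SD of the light by oxygen difference was 0.374 under median normalization, 0.615 in Alexa 532 alone and 0.515 in Alexa 647 alone. The replicate number, given in order of deposit, coincides with the dye orientation and the array series. With it as a replicate block on the 8 arrays as independent, limma called 723 against the reference, 0 for oxygen (305 at an unadjusted p under 0.05) and 0 for light (127). Arrays of the same number correlated at 0.460 to 0.845 across features, and the 2 arrays of a sample at -0.435 to -0.301. Signal over background limits the values, as 47 of 133 named genes had no sample level above background for oxygen and light.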

Other observations

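The lists in this part were formed only after the symbols and values were seen. All 12 named aminoacyl-tRNA synthetase genes had negative values against the reference, with a median of -0.09, and 2 of them, pheS and glyS, passed over all features and 0 when adjusted over the list alone in limma. Only 4 of 12 kept 1 sign in both dye orientations, with a median of -0.23 with the sample in Alexa 532 and 0.03 in Alexa 647. With no background correction and with print-tip loess 9 of 12 were negative. As a set they did not pass (limma camera p = 0.0334, adjusted p = 0.167 over 5 lists, adjusted p = 0.728 with an estimated correlation). Of 6 histidine synthesis genes 5 had negative values, but 1 of 6 kept 1 sign in both orientations, with medians of -0.26 and 0.02 (limma camera adjusted p = 0.378), as had 2 of 3 histidine utilisation genes, none of which was above background, and all 3 thiamine genes (adjusted p = 0.609), where 1 of 3 kept 1 sign in each list. Of 15 genes for carbamoyl phosphate, aromatic and other amino acids 8 had positive and 7 negative values (adjusted p = 0.779). None of these 5 lists passed for oxygen or for light.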
